A study of Mus musculus with 29 samples.

How the data were processed

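RNA-seq was done on bone marrow cells of C57BL/6 mice, sorted into LT-HSC (long-term haematopoietic stem cells), ST-HSC (short-term haematopoietic stem cells) and the multipotent progenitor populations MPP3 and MPP4. The mice carried a Dnmt3a mutation or were controls, and were young animals sampled 6 weeks after pIpC, a double-stranded RNA analogue that is used to switch on the Mx1-Cre recombinase. The mutant allele is not given in the sources used here. Total RNA was isolated with the RNeasy Micro kit and polyA RNA was sequenced, per the labels' protocols. The 29 libraries fell into 8 groups by the titles: 4 control and 3 mutant LT-HSC, 3 control and 4 mutant ST-HSC, 3 control and 4 mutant MPP3, and 4 control and 4 mutant MPP4. The design text counts 3 mutant MPP3 libraries, whereas the sample list holds 4, and all 4 were used. The titles of the mutant ST-HSC libraries give Dnmt3a without the abbreviation for mutant, and their genotype was read from the title and the letter in the description. Each description also holds 1 of 8 numbers, 4 for mutant and 4 for control libraries, which recur across populations. Nothing in the labels says that a number is an animal or that replicates came from separate animals, so p-values here measure only the spread between these samples, which may be technical.

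The values used were deposited expected counts per gene, held as whole numbers for 38924 Ensembl gene identifiers, and no further rounding changed them. Per the submitters' processing notes, RSEM 1.2.12, Bowtie2 2.2.0, SAMtools 0.1.18, edgeR 3.5.3 and the GRCm38 build were used, with the order and role of each tool not given in the sources used here. RSEM shares reads that match several genes between those genes, so the values of near-identical copies, such as immunoglobulin variable segments, Xlr3 paralogs and haemoglobin genes, are uncertain. Symbols and coordinates came from the GENCODE annotation of GRCm38, in which 37607 identifiers were matched by identifier and 1317 were not. Unmatched identifiers are printed as they stand and have no coordinates here. The unmatched identifiers held 0.87% to 1.25% of each library's counts and stayed in the library totals.

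Totals ran from 6133994 to 10374672 counts per library, with a median of 8154500, and 14302 to 17905 genes had a count. At these depths a count of 0 allows up to 0.289 to 0.489 CPM (counts scaled to a common library size), taking 3 counts as the floor of each library. Such floors cover counting error only, because PCR copies are not independent molecules. The mitochondrial rRNA genes held 13.41% to 31.24% of the counts, and Gm42418, an rRNA-like gene, held 3.898% to 7.426%. All 39 pairs of replicates within groups differed by more than sampling noise, with a chi-square per degree of freedom of 21.65 to 78.61, so each library was counted once. Xist had 27833 to 74409 counts in every library, while Ddx3y and Eif2s3y had at most 2 counts and Kdm5d had 0, so a sex term could not be fitted. Uty had 23 to 50 counts in every library despite the other Y-linked genes.

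Each mutant comparison used only the libraries of its population, in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr (10 counts, total of 15), and the quasi-likelihood test. The average of the 4 mutant effects was tested over all 29 libraries with 8 group means in limma 3.58.1, using voom weights and the number in the description as a random block, whose consensus correlation was -0.000528. Whether the mutant effect differed between populations was tested with edgeR's quasi-likelihood F test with 3 degrees of freedom. Control populations were compared in 1 edgeR fit of the 14 control libraries, which share an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Log2 CPM values used a prior count of 2, and levels in CPM used TMM-scaled library sizes. A fold against a group with 0 counts in every library was computed from the floor of 3 counts per library and is given as a lower bound.

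Gene groups were 27 lists written before the data were examined, as were the comparisons, tests, naming rule and the alternative settings named first below. They covered long-term HSC genes, lymphoid priming, granulocyte-monocyte priming, megakaryocyte-platelet, erythroid, HSC ageing, interferon-stimulated genes, TNF and NF-kB response, immediate-early and dissociation stress, cytokine and inflammatory receptors, and DNA replication and S phase. Others were G2 and mitosis, quiescence regulators, p53 targets, DNA methylation machinery, Hox and cofactors, oxidative phosphorylation, glycolysis, ribosome biogenesis and Myc, and unfolded protein and integrated stress response. The remaining lists held markers of mature B cells, mature T and NK cells, neutrophils, macrophages, dendritic cells, basophils with mast cells and eosinophils, and stroma with endothelium. Each list was tested two-sided with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Adjustment ran over the 135 tests of 27 lists in the 4 mutant comparisons and the average, and over the 108 tests of the 4 control comparisons. The level of a list in a library was the mean of log2(CPM + 1) over its members.

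Named genes followed a fixed rule. Dnmt3a was always given. Among genes past the threshold the 10 with the smallest p in each direction were taken, or 5 per direction for control comparisons, leaving out Xist, Tsix and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, predicted gene models, Rik genes and pseudogenes. Where no gene passed in a direction, the 5 with the smallest p were given as not passing. From each list up to 4 members with the smallest p were taken, and for the interaction the 10 genes with the smallest p. Some genes that the rule takes are not reported here. Genes and markers named outside the rule are S100a8, Hbb-bs, Cd79a, Igkc, Jchain, Prdm1, the members of the Xlr family, and the genes of the last part of the closing section, all chosen after their values were seen.

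Correlations of mutant effects between populations were computed across genes and set beside the values from all 35 splits of the 8 numbers into 4 and 4. Other splits of the libraries were refitted for every comparison: all 35 for each pair of groups, and 100 drawn splits, with genotype shuffled within each population, for the average and the interaction. For the lists in the averaged comparison, 50 splits were drawn first and 40 later to shorten the computing time, before 100 were used. Each fit was tested on simulated data made from the real means and library sizes, with 200 genes changed by known folds. Genes were drawn independently of each other, so differences between libraries that many genes share were not simulated. The shares of genes called may therefore be too high for the real data. Other settings written before the data were examined were no filter and a filter of 1 CPM, median-of-ratios scaling, DESeq2 1.42.0, limma-voom with quality weights, a fit of all 29 libraries, a batch term from the first digits of the number in the description, blocks on the replicate or description number, lists without members that another list holds, and leaving out each library or number. Added after seeing the data were fits without the 3 control LT-HSC libraries over 100 CPM of S100a8, a neutrophil covariate, removal of 254 immunoglobulin and 5 rRNA-like genes before scaling, and fits without the 2 libraries with the fewest detected genes.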

Results

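RNA-seq counts were compared in LT-HSC, ST-HSC, MPP3 and MPP4 cells from the bone marrow of control and Dnmt3a-mutant mice, 6 weeks after pIpC. The series title places the work in a study of how Dnmt3a-mutant stem cells become malignant in aged marrow, and these libraries are from the young animals. The 29 libraries comprised 4 control and 3 mutant LT-HSC, 3 control and 4 mutant ST-HSC, 3 control and 4 mutant MPP3, and 4 control and 4 mutant MPP4 samples. Total counts ran from 6438821 to 8234571 in control and 8040593 to 9416995 in mutant LT-HSC, and from 6133994 to 8634517 in control and 6323478 to 7295044 in mutant ST-HSC. They ran from 6423971 to 10368920 in control and 6418833 to 10116135 in mutant MPP3, and from 6659290 to 10374672 in control and 7410008 to 8740114 in mutant MPP4. Values are TMM-scaled CPM, given as mean ± SD.

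Dnmt3a encodes a de novo DNA methyltransferase and is the gene that the mutant mice carry altered (ENSMUSG00000020661, GRCm38 chromosome 12, 3806007 to 3914443). Its RNA was at 121 ± 36.7 CPM in control LT-HSC (n = 4) and 128 ± 8.18 in mutant LT-HSC (n = 3). In ST-HSC the values were 131 ± 20.7 in controls (n = 3) and 125 ± 22.5 in mutants (n = 4). In MPP3 they were 114 ± 14.5 (n = 3) and 130 ± 61.7 (n = 4), and MPP4 had 124 ± 6.79 in controls and 144 ± 21.4 in mutants (n = 4 each). The log2 differences, mutant minus control, were 0.07 ± 0.232 (SE) in LT-HSC, -0.07 ± 0.229 in ST-HSC, 0.19 ± 0.304 in MPP3 and 0.22 ± 0.175 in MPP4. The adjusted p values in edgeR were 0.973, 0.998, 1 and 0.999. Leaving out 1 library turned the sign in 3 populations. In LT-HSC it was -0.089 without control replicate 1 and -0.00221 without control replicate 3. In ST-HSC it was 0.0327 without mutant replicate 2 and 0.0206 without control replicate 1. In MPP3 it was -0.203 without mutant replicate 1, the library with 222 CPM. Whole-gene counts cannot tell whether the RNA came from the altered allele or which exons it held, so the level does not check the genotype labels.

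**Figure D1:**
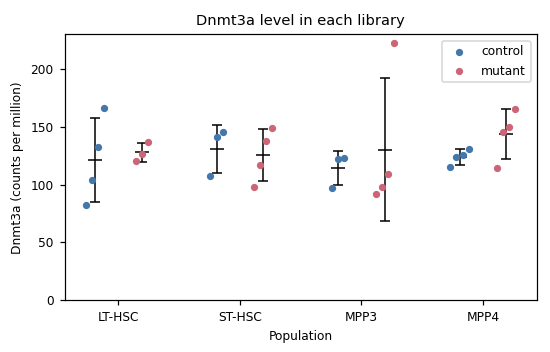
Dnmt3a RNA in CPM (vertical axis) in each library of LT-HSC, ST-HSC, MPP3 and MPP4, with control in blue and mutant in red, a point per library and bars for the mean ± SD. Control and mutant points overlap in each population, and 1 mutant MPP3 library stands at 222.

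The populations were first compared with each other in the 14 control libraries. Control ST-HSC had more RNA of Flt3, the receptor for FLT3 ligand (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489), than control LT-HSC. It was at 155 ± 45.7 CPM against 62.4 ± 10.3, a 2.51-fold rise (adjusted p = 0.00863, n = 3 and 4). The interleukin-1 receptor gene Il1r1 rose 4.23-fold, from 8.6 ± 1.38 to 36 ± 5.68 (0.00561), and S1pr3, a sphingosine 1-phosphate receptor gene, rose 14.6-fold, from 0.782 ± 0.613 to 11.6 ± 2.92 (0.00452). Vldlr rose 3.99-fold and Ikzf2 2.23-fold. The platelet chemokine gene Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383) fell 22.8-fold, from 51.4 ± 17.8 to 2.28 ± 1.76 (0.00863). Cavin2 fell 35.4-fold, Iqgap3 4.69-fold, and Sfxn5 at least 18.3-fold, to 0 counts in the 3 ST-HSC libraries. The von Willebrand factor gene Vwf was 2.94-fold lower, at 45 ± 3.93 against 134 ± 17.3 (0.0217).

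By list, megakaryocyte-platelet genes fell in ST-HSC, with 17 of 20 members lower (adjusted p = 3.29e-15, and 0.00206 with an estimated correlation). Of these members, 4 passed over all genes and 9 when adjusted over the list alone. HSC ageing genes were lower in 16 of 19 members, with 2 past the threshold and 5 when adjusted over the list alone (9.05e-09, and 0.00206 with an estimated correlation). The 2 that passed, Vwf and Cavin2, are also megakaryocyte-platelet members, and both lists hold Selp and Itgb3, so their calls are not separate. Lists without shared members were not run for the control comparisons. G2 and mitosis genes were lower in 24 of 24 members, including Mki67 at 594.4 ± 158 against 1725 ± 949 (adjusted p = 5.22e-23, and 0.0543 with an estimated correlation). Adjusted over the list alone, 17 passed. DNA replication genes were lower in 24 of 28 members (1.88e-05, and 0.172 with an estimated correlation). The neutrophil list was lower in 15 of 15 members (4.38e-10), the erythroid list in 20 of 22 (1.88e-05), the granulocyte-monocyte priming list in 19 of 24 (0.00269) and the basophil, mast cell and eosinophil list in 11 of 12 (0.00213). With an estimated correlation the adjusted p values of these 4 were 0.233, 0.423, 0.601 and 0.384. Control LT-HSC replicates 1, 2 and 3 held 2260, 583 and 349 CPM of the neutrophil gene S100a8 and replicate 4 held 3.67, against 41.47 ± 34.6 in control ST-HSC. Lymphoid priming genes were higher in 21 of 25 members (0.00322, and 0.423 with an estimated correlation). Stroma and endothelium genes were higher in 9 of 13 (9.61e-05, and 0.173 with an estimated correlation). Among them the endothelial cadherin gene Cdh5 passed at 22.1 ± 19.8 against 0.214 ± 0.429.

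In all, 13 genes rose and 13 fell of 14937 tested, with 1514 at an unadjusted p under 0.05. The count rested on single libraries: it was 17, 8, 1 and 217 without LT-HSC replicates 1, 2, 3 and 4, and 47, 11 and 5 without ST-HSC replicates 1, 2 and 3. Of the 9 genes given above for their small p, which leave out Vwf, S1pr3 passed in each of these fits. The other 8 were lost without LT-HSC replicate 3 (adjusted p up to 0.0747), and 4 of them without ST-HSC replicate 2 (Ikzf2 0.0888, Iqgap3 0.0638, Vldlr 0.0629, Sfxn5 0.0528). Without ST-HSC replicate 3, Ikzf2 was at 0.0863 and Flt3, Sfxn5 and Iqgap3 at 0.0653. Ikzf2 was at 0.0871 without LT-HSC replicate 2 and at 0.0585 without LT-HSC replicate 1. Without the 3 LT-HSC libraries over 100 CPM of S100a8, a lone control LT-HSC library is left, too few for a count. Each of the 9 genes kept its direction there. The log2 difference was 5.28 for S1pr3 against 3.863 in the full fit, and -4.7 against -4.513 for Pf4. It was 1.43 against 1.327 for Flt3, but 1.46 against 1.995 for Vldlr and 0.789 against 1.159 for Ikzf2.

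**Figure D2:**
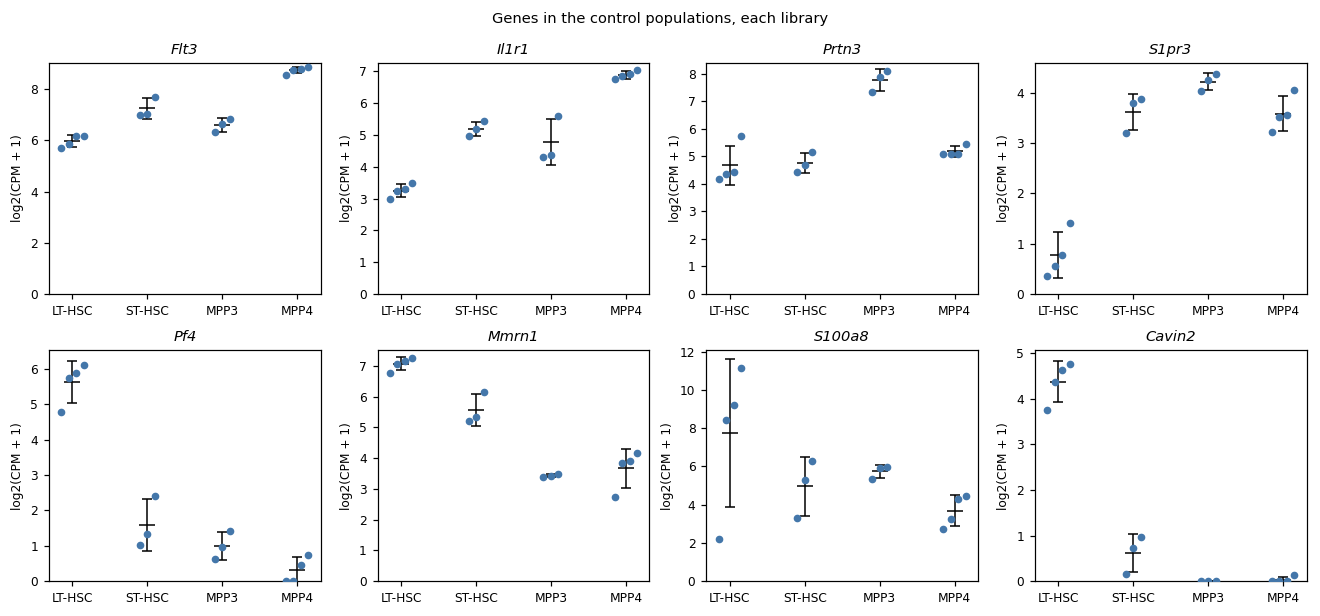
Level of 8 genes in the 14 control libraries as log2(CPM + 1) on the vertical axis, by population on the horizontal axis, with 1 point per library and bars for the mean ± SD. Flt3 stands highest in MPP4 at 427 ± 35.1 CPM, and S100a8 spreads from 3.67 to 2260 CPM within LT-HSC.

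MPP3 cells are known for a granulocyte and monocyte bias. Prtn3, the neutrophil granule proteinase 3 gene (ENSMUSG00000057729, chromosome 10, 79874476 to 79883174), rose in control MPP3 against LT-HSC. The rise was 8.3-fold, from 27.1 ± 16.6 to 223 ± 57.9 CPM (adjusted p = 5.2e-05, n = 3 and 4). Nkg7 rose 5.84-fold to 141 ± 27.7 (6.92e-05), Adgrg3 3.61-fold, S1pr3 22.3-fold, Tespa1 10.1-fold, and Cebpa, a myeloid transcription factor gene, 9.63-fold from 2.16 ± 1.19 to 20.8 ± 5.17 (0.00275). The multimerin gene Mmrn1 fell 13.7-fold, from 135 ± 19 to 9.79 ± 0.347 (1.67e-05). Itsn1 fell 3.93-fold, Nbea 15.4-fold, the stem-cell transcription factor gene Mecom 3.82-fold (0.000851) and Cavin2 at least 51.9-fold, to 0 counts in the 3 MPP3 libraries.

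Long-term HSC genes were lower in MPP3 in 21 of 22 members, with 10 past the threshold over all genes and 18 when adjusted over the list alone. The adjusted p of the list was 4.99e-26, and 0.00211 with an estimated correlation. Among its members Slamf1, a receptor gene used to sort LT-HSC, was at 1.34 ± 1.24 against 24.2 ± 7.22 CPM (0.0166). HSC ageing genes were lower in 15 of 19 members (9.8e-18, and 7.82e-05 with an estimated correlation) and megakaryocyte-platelet genes in 19 of 20 (3.22e-17, and 0.00115 with an estimated correlation). Interferon-stimulated genes were lower in 29 of 32 members, with 3 past the threshold, Iigp1 at 3.3 ± 1.6 against 23.7 ± 3.73, Oasl2 and Isg15 (4.28e-09, and 0.0168 with an estimated correlation). Hox genes and cofactors were lower in 15 of 16 members, with 2 past the threshold and 6 when adjusted over the list alone (8.22e-08, and 0.0492 with an estimated correlation). Granulocyte-monocyte priming genes were higher in 20 of 24 members, 11 of them past the threshold when adjusted over the list alone (1.46e-16, and 0.129 with an estimated correlation). Unfolded protein response genes were higher in 14 of 17, with Calr at 587 ± 95.8 against 208 ± 40.7 and Xbp1 at 192 ± 37.7 against 66.4 ± 18.2 (3.55e-09, and 0.125 with an estimated correlation). Of genes of antibody-secreting cells, which also express Xbp1, Igkc was at 3167 ± 2310 against 83.26 ± 93.2 (0.247), Jchain at 359.3 ± 196 against 6.42 ± 8.71 (0.288) and Prdm1 at 29.44 ± 20.3 against 3.016 ± 2.73 (0.054), none past the threshold in edgeR. Also higher at the preset correlation were lymphoid priming (1.12e-05), oxidative phosphorylation (1.99e-05), G2 and mitosis (2.87e-05), ribosome biogenesis and Myc (7.97e-05), DNA replication (0.00569) and glycolysis (0.0112). The adjusted p values with an estimated correlation were 0.233, 0.31, 0.407, 0.216, 0.368 and 0.233. Lower were the neutrophil (5.38e-06), immediate-early (0.000193), erythroid (0.000661) and TNF and NF-kB lists (0.0364), with adjusted p = 0.398, 0.185, 0.548 and 0.258 with an estimated correlation. S100a8 was at 53.42 ± 11.7 CPM in control MPP3 against 798.4 ± 1000 in control LT-HSC. In all, 85 genes rose and 133 fell (edgeR), with 1960 at an unadjusted p under 0.05. The count was 123, 117 and 63 without MPP3 replicates 1, 2 and 3, and 118 and 138 without LT-HSC replicates 2 and 3. Without the 3 libraries high in S100a8 a lone control LT-HSC library is left, too few for a count.

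MPP4 cells are known for a lymphoid bias and high Flt3. Flt3 rose 6.85-fold in control MPP4 against LT-HSC, to 427 ± 35.1 CPM (adjusted p = 2.46e-07, n = 4 each), and Il1r1 13.8-fold, to 118 ± 10.4 (3.8e-07). Adgrg3 rose 4.44-fold, Ramp1 5.38-fold, the histone macroH2A gene H2afy 5.87-fold (8.97e-06), and Notch1 3.75-fold to 186 ± 43.8 (3.46e-05). Satb1, the gene of a chromatin organiser of lymphoid cells, rose 12.7-fold from 23.3 ± 16.8 to 294 ± 23.9 (0.000654). Sox6 fell 17.4-fold, from 106 ± 37.6 to 6.03 ± 0.866 (5.23e-07), Tgfbr3 17.3-fold, Slc18a2 7.98-fold, Mfsd2b 21.4-fold and Mmrn1 10.6-fold (1.21e-06). Gata2, a stem-cell transcription factor gene, fell 5.13-fold to 38.9 ± 10 (2.12e-05), and Slamf1 at least 66.1-fold, to 0 counts in the 4 MPP4 libraries.

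Megakaryocyte-platelet genes were lower in MPP4 in 20 of 20 members, 14 past the threshold over all genes and 18 when adjusted over the list alone. Among them the integrin gene Itgb3 was at 4.4 ± 0.932 against 47.3 ± 10.4 CPM. The adjusted p of the list was 8.28e-40, and 7.22e-05 with an estimated correlation. HSC ageing genes were lower in 17 of 19 members (4.99e-26, and 7.22e-05 with an estimated correlation) and long-term HSC genes in 20 of 22 (6.52e-16, and 0.0156 with an estimated correlation). Lymphoid priming genes were higher in 19 of 25 members, 10 past the threshold and 11 when adjusted over the list alone (5.29e-16, and 0.0405 with an estimated correlation). The erythroid list was lower in 22 of 22 members, 13 past the threshold (4.99e-26, and 0.063 with an estimated correlation). The neutrophil list was lower in 15 of 15, 2 past the threshold (4.18e-10, and 0.236 with an estimated correlation), and S100a8 was at 13.5 ± 7.47 CPM in control MPP4. Ribosome biogenesis genes were higher (0.00315), and macrophage (0.00323), immediate-early (0.0106), stroma (0.016) and basophil (0.0329) lists lower, with adjusted p = 0.368, 0.407, 0.376, 0.423 and 0.548 with an estimated correlation. In all, 229 genes rose and 398 fell (edgeR), with 2314 at an unadjusted p under 0.05. The count was 415 without LT-HSC replicate 2, and 412 and 367 without MPP4 replicates 2 and 4. Without the 3 libraries high in S100a8 a lone control LT-HSC library is left, too few for a count.

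Control MPP4 and MPP3 were set against each other to compare the lymphoid and the myeloid progenitor. Flt3 was 4.38-fold higher in MPP4, at 427 ± 35.1 against 97.1 ± 17.6 CPM (adjusted p = 9.68e-05, n = 4 and 3), Notch1 3.44-fold (0.000772), Gpr171 3.12-fold, Stxbp4 3.06-fold and Zfhx3 2.9-fold. Prtn3 was 6.33-fold lower, at 35.3 ± 4.96 (0.000458), and the erythroid transcription factor gene Gata1 39.1-fold lower, at 0.36 ± 0.176 against 14.3 ± 6.03 (0.000587). Apoe was 6.43-fold lower, Mt1 33.5-fold, and the unmatched identifier ENSMUSG00000094062 at least 53.4-fold (0.000458). Unfolded protein response genes were lower in 16 of 17 members, 6 past the threshold, among them Xbp1 and Calr (1.35e-14, and 0.0407 with an estimated correlation). Of genes of antibody-secreting cells, Igkc was at 2.649 ± 1.98 in MPP4 against 3167 ± 2310 in MPP3 (0.0821), Jchain at 0 against 359.3 ± 196 (0.159) and Prdm1 at 2.147 ± 1.37 against 29.44 ± 20.3 (0.0318, past the threshold). Megakaryocyte-platelet genes were lower in 15 of 20 (2.17e-09, and 0.0104 with an estimated correlation). Interferon-stimulated genes were higher in 26 of 32 members, with Iigp1 past the threshold (1.94e-07, and 0.0359 with an estimated correlation). Erythroid genes were lower in 22 of 22 members (9.52e-20) and granulocyte-monocyte priming genes in 21 of 24, 6 past the threshold (1.17e-17), where the adjusted p was 0.0996 and 0.137 with an estimated correlation. Lymphoid priming was called higher (7.36e-06, and 0.225 with an estimated correlation) with 15 of 25 members higher, but the mean of its log2 differences was -0.27 against a median of 0.84. Hox genes (3.44e-05) and long-term HSC genes (0.0244) were also called higher, with adjusted p = 0.125 and 0.407 with an estimated correlation. The macrophage, basophil, mature B cell, G2 and mitosis, stroma, neutrophil, HSC ageing, oxidative phosphorylation and glycolysis lists were called lower at the preset correlation, and none of these 9 calls held with an estimated one. In all, 60 genes were higher and 110 lower (edgeR), with 1665 at an unadjusted p under 0.05. The count was 78 and 102 without MPP3 replicates 1 and 3, and 96, 113, 102 and 92 without MPP4 replicates 1, 2, 3 and 4. Over the 4 control comparisons, 55 of the 108 list tests passed, of which 14 held with an estimated correlation. Quiescence regulators, p53 targets, DNA methylation machinery, cytokine receptors, mature T and NK cells and dendritic cells passed in none of them.

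The mutant was then compared with the control within each population. In LT-HSC, the 22 tested genes of the long-term HSC list were all higher in the mutant libraries. Slamf1 was at 40 ± 12.4 against 24.2 ± 7.22 CPM (n = 3 and 4), Mecom at 138 ± 13.9 against 95 ± 29.7 and Mycn at 72.5 ± 12.6 against 45.4 ± 14. The list rose (adjusted p = 2.48e-06, and 0.455 with an estimated correlation). Megakaryocyte-platelet genes were higher in 15 of 21 members, with Cavin2 at 36.4 ± 8.68 against 20.4 ± 5.97 (0.0121, and 0.479 with an estimated correlation), a call that ended at 0.111 without members that another list holds. Ribosome biogenesis and Myc genes were higher in 20 of 24, with Fbl at 73.5 ± 4.95 against 55.5 ± 5.97 (0.022, and 0.479 with an estimated correlation). No member of the 27 lists passed over all genes in any mutant comparison, and no member of these 3 passed when adjusted over its list alone.

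Genes of maturing blood cells were lower in the mutant LT-HSC libraries. Erythroid genes were lower in 21 of 22 members, 13 of them past the threshold when adjusted over the list alone (adjusted p = 8.25e-16, and 0.43 with an estimated correlation). The Rh-associated gene Rhag was at 1.45 ± 0.283 against 45 ± 38.7, and the haem synthesis gene Alas2 at 4.75 ± 2.03 against 115 ± 114. Mature B cell genes were lower in 13 of 13 members, 10 of them past the threshold when adjusted over the list alone, with Cd79b at 7.8 ± 1.58 against 25.3 ± 11.8 (4.32e-14, and 0.43 with an estimated correlation). Granulocyte-monocyte priming genes were lower in 22 of 23 members, with Csf3r at 97.6 ± 17.8 against 251 ± 118 (2.52e-12, and 0.455 with an estimated correlation). Neutrophil genes were lower in 15 of 15, with Cxcr2 at 49.6 ± 6.05 against 178 ± 100 (1.32e-08, and 0.479 with an estimated correlation). The control libraries differed in markers of other cells. In control replicates 1, 2, 3 and 4, S100a8 was at 2260, 583, 349 and 3.67 CPM. The haemoglobin gene Hbb-bs was at 9280, 2550, 2950 and 186, and the B cell gene Cd79a at 79.2, 22, 16.4 and 1.97. In mutant replicates 1, 2 and 3, S100a8 was at 17.1, 67.2 and 5.83, Hbb-bs at 205, 258 and 140, and Cd79a at 3.11, 1.73 and 1.14. The mean level of the neutrophil list was 5.82 ± 2.71 in controls and 3.127 ± 1.02 in mutants, as log2(CPM + 1). That of the erythroid list was 6.561 ± 1.77 and 4.034 ± 0.38, and of the mature B cell list 3.876 ± 1.12 and 2.287 ± 0.371.

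TNF and NF-kB response genes were lower in 16 of 22 members, with the chemokine gene Cxcl2 at 0.502 ± 0.336 against 38.1 ± 32.5 CPM (adjusted p = 0.000162, and 0.43 with an estimated correlation). Immediate-early genes were lower in 14 of 20, with Btg2 at 17.7 ± 7.7 against 76.3 ± 41.6 (0.0266, and 0.558 with an estimated correlation). G2 and mitosis genes were lower in 22 of 24 members, with Mki67 at 960.7 ± 200 against 1725 ± 949 (0.000176, and 0.57 with an estimated correlation). Lymphoid priming genes were lower in 16 of 22 members, with Blnk at 2.64 ± 2.01 against 20.6 ± 12.1 and the interleukin-7 receptor gene Il7r at 0 against 8.54 ± 9.84, at least 24.6-fold lower (0.0056, and 0.455 with an estimated correlation). Basophil, mast cell and eosinophil genes were lower in 9 of 10 members, with the histidine decarboxylase gene Hdc at 2.63 ± 2.12 against 48.9 ± 32.2 (2.41e-05, and 0.458 with an estimated correlation). Macrophage genes were lower in 11 of 12 (2.8e-05) and dendritic cell genes in 7 of 9 (0.00385), with adjusted p = 0.433 and 0.43 with an estimated correlation. Adjusted over the list alone, 2 members fell in each of the granulocyte-monocyte and TNF lists, 3 in the dendritic list and 1 in the lymphoid list. Without the 3 control libraries over 100 CPM of S100a8, which leaves 1 control and takes the spread from all other libraries, 13 of the 14 list calls in LT-HSC ended. The exception, the neutrophil list, turned to higher in the mutant (0.0104).

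Single libraries ended calls of the lymphoid, megakaryocyte, ribosome and immediate-early lists. Without mutant LT-HSC replicates 1, 2 and 3, 2, 1 and 1 of the calls were lost (adjusted p up to 0.0878, 0.144 and 0.0902). Without control replicates 1, 2 and 3, 3, 3 and 1 were lost (up to 0.116, 0.0973 and 0.0799). The other 10 lists passed in each of these fits. No single gene passed in mutant LT-HSC in edgeR, of 13922 tested, with 1136 at an unadjusted p under 0.05, while DESeq2 called 292 (13 higher, 279 lower) and limma-voom with quality weights 0. The 5 lower genes with the smallest p all had an adjusted p of 0.102. Of these, the repressor gene Bcl6 was at 3.95 ± 0.465 against 33.1 ± 21.8 CPM (log2 difference -3.07 ± 0.508 SE) and Tnf at 0.387 ± 0.356 against 14.8 ± 10.3. Jaml was at 0.0334 ± 0.0578 against 7.61 ± 5.9, and another was the unmatched identifier ENSMUSG00000071286. Among the higher ones were Cbx6 at 58 ± 6.57 against 29.8 ± 3.9 (0.332), and Pygm and Mgat4b (0.337 each). Echdc2 was at 1.99 ± 0.508 against 0 in each control (0.313). Without control LT-HSC replicate 4, the library with 3.67 CPM of S100a8, 384 genes passed, among them Bcl6 (0.000556), Jaml (0.00114), Tnf (0.0012), Echdc2 (0.0249) and Pygm (0.0376). Without control replicate 1 or replicate 3, 1 gene passed. Of simulated genes changed 4-fold, 64.6% were called. Genes were drawn independently there, so the shared differences between control libraries were not simulated and the share may be too high.

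**Figure D3:**
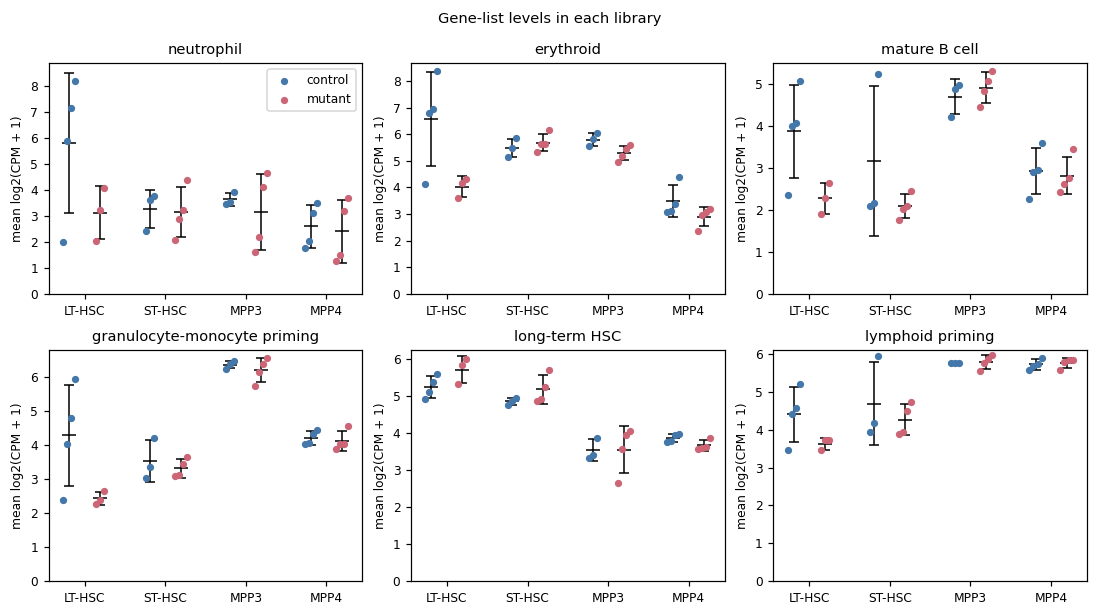
Mean log2(CPM + 1) over the members of 6 gene lists (vertical axis) in each library by population, with control in blue and mutant in red, 1 point per library and bars for the mean ± SD. In LT-HSC the control libraries spread over the neutrophil list with a mean of 5.82 ± 2.71, against 3.127 ± 1.02 in mutants.

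In mutant ST-HSC, oxidative phosphorylation genes were higher in 26 of 33 members (adjusted p = 0.000176, and 0.43 with an estimated correlation). The cytochrome c oxidase subunit gene Cox5b was at 51.3 ± 18.2 against 22.6 ± 4.17 CPM and the complex I gene Ndufb5 at 24.7 ± 4.05 against 12.4 ± 3.17 (n = 4 and 3). Ribosome biogenesis and Myc genes were higher in 17 of 24 members, with the spermidine synthase gene Srm at 67.6 ± 21.5 against 30.9 ± 5.81 (0.00989, and 0.433 with an estimated correlation). Myc itself was at 362 ± 59.9 against 255 ± 24.9. Glycolysis genes were higher in 13 of 18 members, with Ldha at 198 ± 5.86 against 150 ± 31 (0.0402, and 0.538 with an estimated correlation). Long-term HSC genes were higher in 15 of 22 (0.0402, and 0.57 with an estimated correlation). That call was lost without mutant replicates 2 (0.518) and 4 (0.147) and control replicates 1 (0.233) and 2 (0.0513). Mature B cell genes were lower in 8 of 8 members, with Cd79a at 1.95 ± 2.49 against 22 ± 35.8 (4.31e-05, and 0.455 with an estimated correlation). The mature B cell level of 1 control library, 5.235 as log2(CPM + 1), lay above the mutant mean of 2.091 ± 0.283, and that list's call was lost without control ST-HSC replicate 1 (0.403). Lymphoid priming genes were lower in 15 of 22 members, with Mef2c at 92.2 ± 28.9 against 159 ± 32.3 (0.0315, and 0.626 with an estimated correlation), a direction that reversed without control ST-HSC replicate 1 (0.854). G2 and mitosis genes were lower in 21 of 24 (0.0499, and 0.684 with an estimated correlation). Basophil, mast cell and eosinophil genes were lower in 4 of 4 members (0.0499) and stroma and endothelium genes in 9 of 11 (0.05, just under the threshold), with adjusted p = 0.43 and 0.538 with an estimated correlation. A stroma gene passed when adjusted over its list alone. Without members that another list holds, the long-term HSC (0.0786), G2 and mitosis (0.0561), basophil (0.0687) and stroma (0.0561) calls ended, and with median-of-ratios scaling the last 3 did (0.0504 each).

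Of the 9 ST-HSC list calls, oxidative phosphorylation passed in every fit that left out 1 library. Calls lost without mutant ST-HSC replicates 1, 2, 3 and 4 numbered 4, 5, 2 and 4 (adjusted p up to 0.294, 0.566, 0.13 and 0.147). Without control replicates 1, 2 and 3 they numbered 5, 5 and 2 (up to 0.854, 0.364 and 0.373). No single gene passed in edgeR of 13381 tested, with 499 at an unadjusted p under 0.05, and DESeq2 and limma-voom with quality weights also called 0. The smallest p of higher genes were those of Rras, Guk1 at 20 ± 2.16 against 6 ± 2.04 CPM, Ube3b at 89.8 ± 17.3 against 45.9 ± 4.6, Vegfb and Psmd2. Those of lower genes were Phf13, the chemokine gene Cxcl12 at 2.1 ± 1.29 against 25.5 ± 29.9, Ccr9 at 2.12 ± 1.29 against 25.3 ± 37.9, Inpp4a and ENSMUSG00000098168. Each of the 10 had an adjusted p of 0.998. Of simulated genes changed 4-fold, 42.6% were called.

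In mutant MPP3, 1 gene passed, the identifier ENSMUSG00000094062, which has no symbol or coordinates in the annotation used. It was at 30.1, 17.2 and 11.3 CPM in control replicates 1, 2 and 3 and at 0 counts in the 4 mutant libraries, at least 53.9-fold lower (adjusted p = 0.0442). The heavy-chain variable gene Ighv6-3 was at 27.3, 25 and 16.6 CPM in the same controls and at 0, 0, 0 and 1.09 in the mutants. Erythroid genes were lower in 20 of 22 members (adjusted p = 0.000144, n = 4 and 3). Megakaryocyte-platelet genes were lower in 12 of 16 members, with Gp1ba at 2.2 ± 1.5 against 6.41 ± 2.64 (0.0402, and 0.259 without members that another list holds). Basophil, mast cell and eosinophil genes were lower in 10 of 13, with the protease gene Prss34 at 0.867 ± 1.32 against 6.53 ± 7.58 (0.0257), and stroma and endothelium genes in 6 of 7, with Pdgfrb at 8.84 ± 3.86 against 17.2 ± 5.54 (0.0349). All 4 lists were at an adjusted p = 0.43 with an estimated correlation, and no member passed when adjusted over its list alone. S100a8 was at 53.42 ± 11.7 CPM in control and 56.18 ± 49.9 in mutant MPP3, and Hbb-bs at 614.2 ± 73.5 and 572.6 ± 292.

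The identifier ENSMUSG00000094062 in MPP3 was called by DESeq2 as well (adjusted p = 9.37e-12), and was at 0.0652 with a batch term from the description numbers. It missed the threshold in edgeR without mutant replicates 2, 3 and 4 (0.0665, 0.0625 and 0.107) and without control replicates 1, 2 and 3 (1, 1 and 0.0835). Of the 4 list calls, 1, 1, 3 and 3 were lost without mutant replicates 1, 2, 3 and 4 (up to 0.0597, 0.0612, 0.163 and 0.135). Without control replicates 1 and 2, 3 and 2 were lost (up to 0.306 and 0.391). Among 13572 genes, 296 had an unadjusted p under 0.05, and DESeq2 and limma-voom with quality weights called 2 each. No gene rose past the threshold. The smallest p of higher genes were those of Dst, at 90.6 ± 28 against 42.1 ± 3 CPM, Vasn, at 17.7 ± 4.12 against 5.29 ± 1.19, Tmem65, Fam49a and Shroom4, each with adjusted p = 1. Of simulated genes changed 4-fold, 53.8% were called.

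In mutant MPP4, erythroid genes were lower in 16 of 17 members, 2 of them past the threshold when adjusted over the list alone (adjusted p = 1.92e-05, and 0.455 with an estimated correlation; n = 4 each). Dendritic cell genes were lower in 9 of 10 members, 1 of them past the threshold when adjusted over the list alone (0.000873, and 0.43 with an estimated correlation). Ly86 was at 1.22 ± 0.225 against 7.88 ± 5.28 CPM and the integrin gene Itgax at 2.17 ± 1.58 against 6.23 ± 3.06. Cytokine and inflammatory receptor genes were lower in 16 of 22 members, with Csf2rb2 at 8.17 ± 1.66 against 18 ± 6.83 (0.0186, and 0.433 with an estimated correlation). Long-term HSC genes were lower in 15 of 20 members, with Hlf at 614 ± 69.2 against 751 ± 29.8 (0.0266, and 0.43 with an estimated correlation), a call that ended at 0.162 without members that another list holds. Unfolded protein response genes were higher in 12 of 16 members, with Pdia4 at 63.5 ± 24 against 40.8 ± 13.6 (0.0363, and 0.626 with an estimated correlation).

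No MPP4 list passed in every fit that left out 1 library. Of the 5 calls, 2, 1 and 3 were lost without mutant replicates 1, 2 and 3 (adjusted p up to 0.214, 0.0846 and 0.164). Without control replicates 1, 2, 3 and 4, 2, 1, 2 and 3 were lost (up to 0.197, 0.0575, 0.262 and 0.173). No single gene passed in edgeR of 13108 tested, with 407 at an unadjusted p under 0.05, while DESeq2 called 5 (2 higher, 3 lower) and limma-voom with quality weights 0. Rorb, the gene of an orphan nuclear receptor, was at 1060 ± 261 against 582 ± 99.6 CPM. The log2 difference was 0.87 ± 0.197 (SE), with adjusted p = 0.999 in edgeR and 0.0496 in DESeq2. The mitotic kinase gene Melk was at 23.2 ± 12.3 against 7.75 ± 3.28, and Sned1, Tmem35b and Csnk2a2 were the other higher genes with the smallest p (0.999 each). Car1, a carbonic anhydrase gene of red cells, was at 0.0974 ± 0.0656 against 4.55 ± 4.2 (0.373, and 0.0139 in DESeq2). Cyren, Ly86, Tmem218 and Anpep followed (0.999 each), of which DESeq2 put Cyren at 0.0169 and Ly86 at 0.0496. Of simulated genes changed 4-fold, 78.1% were called.

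**Figure D4:**
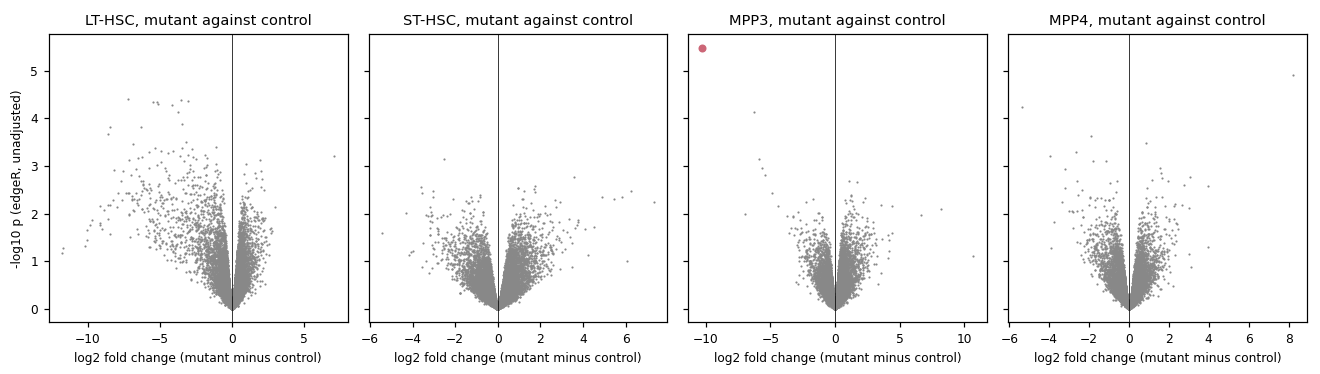
Log2 fold change, mutant minus control (horizontal axis), against -log10 of the unadjusted p in edgeR (vertical axis) for each gene tested in LT-HSC, ST-HSC, MPP3 and MPP4, with points for genes. The only point in red, in MPP3, is the identifier at an adjusted p of 0.0442.

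The mutant effect averaged over the 4 populations was tested over all 29 libraries with limma-voom. The gene with the smallest p was Xlr3b, an X-linked gene of a lymphocyte-regulated family (ENSMUSG00000073125, chromosome X, 73192207 to 73202930). It was at 5.79 ± 4.4 CPM in mutants (n = 15) and 0.993 ± 1.19 in controls (n = 14). The log2 difference was 3.39 ± 0.621 (SE), with an adjusted p of 0.0686. Its mutant mean lay above its control mean in each population. It was at 7.27 ± 5.26 against 1.68 ± 1.57 in LT-HSC and 6.95 ± 6.28 against 1.18 ± 1.64 in ST-HSC. It was at 3.59 ± 2.45 against 0.141 ± 0.244 in MPP3 and 5.7 ± 4.01 against 0.806 ± 0.608 in MPP4. The other higher genes were Vldlr, at 74.9 ± 26.5 against 55.4 ± 32.2, Gcdh, Nat1 and Qrfp (adjusted p = 0.547 each). Lower genes were Ighv6-3 (0.116), Hsd11b1, the gene of a glucocorticoid-activating enzyme (0.242), the RNA sensor gene Tlr7 (0.372), ENSMUSG00000094062 (0.372) and the B cell lectin gene Siglecg (0.454). None of 15915 genes passed, with 913 at an unadjusted p under 0.05, while edgeR without a block called 3 and limma-voom with quality weights 0. The result rested on single numbers of the description: Xlr3b passed without 1708 (0.0165), 1803 (0.0302) or 1819 (0.0224) and was at 0.865 without 1705. Without 1803, 45 genes passed, among them Ighv6-3 (0.0428), Hsd11b1 (0.00542), Tlr7 (0.00503) and Siglecg (0.0151), and 1 gene passed without 1708, 1804 or 1819. The number 1803 includes control LT-HSC replicate 4, the library with 3.67 CPM of S100a8. Without it, the control LT-HSC libraries left were those over 100 CPM of S100a8.

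Averaged over the populations, erythroid genes were lower in 21 of 22 members (adjusted p = 6.43e-21, and 0.215 with an estimated correlation). Mature B cell genes were lower in 14 of 14 (2.41e-11), granulocyte-monocyte priming genes in 22 of 24 (5.83e-11) and lymphoid priming genes in 21 of 25 (0.000345), the last 3 at 0.43 with an estimated correlation. Dendritic cell genes were lower in 12 of 12 members, 3 of them past the threshold when adjusted over the list alone, with Cd209a as an example at a log2 difference of -3.24 (4.45e-08, and 0.215 with an estimated correlation). Basophil, mast cell and eosinophil genes were lower in 12 of 13 members (2.35e-06, and 0.43 with an estimated correlation), neutrophil genes in 15 of 15 (2.41e-05, and 0.458) and macrophage genes in 13 of 14 (0.00385, and 0.433). TNF and NF-kB response genes were lower in 14 of 22 members (0.0155, and 0.43 with an estimated correlation). Cytokine and inflammatory receptor genes were lower in 16 of 22, with Csf2rb2 at -1.01 ± 0.255 (SE) (0.0363, and 0.458), and G2 and mitosis genes in 22 of 24 (0.0266, and 0.655). Ribosome biogenesis and Myc genes were higher in 20 of 24 members (0.000229, and 0.43 with an estimated correlation). Oxidative phosphorylation genes were higher in 23 of 33 (0.00967, and 0.538) and long-term HSC genes in 18 of 22 (0.022, and 0.538). The control LT-HSC libraries high in S100a8 entered this average, and without them 9 of its 14 calls ended or reversed (adjusted p 0.425 to 0.991). The erythroid, mature B cell, dendritic cell, ribosome and oxidative phosphorylation calls were kept. The cytokine receptor call also ended without members that another list holds (0.0786).

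Of these 14 calls, 9 passed in each of the 29 fits that left out 1 library. Long-term HSC was lost in 7 of them (adjusted p 0.0526 to 0.117, highest without mutant MPP3 replicate 4). Cytokine receptors were lost in 8 (0.0555 to 0.182, highest without control MPP3 replicate 2) and G2 and mitosis in 11 (0.0543 to 0.233, highest without control ST-HSC replicate 1). Lymphoid priming was lost without control ST-HSC replicate 1 (0.061), and oxidative phosphorylation without mutant MPP4 replicate 3 (0.0518) or mutant LT-HSC replicate 2 (0.0786). Over the 4 populations and the average, 46 of 135 list tests passed, 11 higher and 35 lower in mutants, and none held with an estimated correlation, where the smallest adjusted p was 0.215.

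Some lists passed in no mutant comparison, with adjusted p given for LT-HSC, ST-HSC, MPP3, MPP4 and the average in that order. Interferon-stimulated genes were at 0.326, 0.841, 0.841, 0.401 and 0.626, and HSC ageing genes at 0.07, 0.442, 0.544, 0.626 and 0.841. DNA methylation machinery was at 0.551, 0.225, 0.991, 0.937 and 0.442, and Hox genes and cofactors at 0.0516, 0.991, 0.326, 0.193 and 0.53. DNA replication was at 0.662, 0.463, 0.137, 0.991 and 0.779, and quiescence regulators at 0.664, 0.55, 0.0559, 0.868 and 0.991. The p53 targets were at 0.717, 0.937, 0.432, 0.837 and 0.771, and mature T and NK cells at 0.441, 0.549, 0.991, 0.771 and 0.219. Among lists that did not pass, some tests went against the list's own median. Neutrophil genes tended lower by the test with a median log2 difference of 0.16 in ST-HSC, 0.24 in MPP3 and 0.35 in MPP4, and so did mature T and NK genes in MPP3 (0.21). Median and mean also differed in sign for quiescence regulators in LT-HSC (0.14 and -0.14), HSC ageing in ST-HSC (-0.09 and 0.08) and basophil genes in MPP4 (0.24 and -0.78).

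Whether the mutant effect differed between populations was tested as an interaction. No gene passed of 15915 in edgeR, with 926 at an unadjusted p under 0.05, while DESeq2 called 48. The smallest p were those of Cd53, a leukocyte tetraspanin gene (ENSMUSG00000040747, chromosome 3, 106759921 to 106790149), and Cxcl2 (adjusted p = 0.256 each). Next were Clec5a, Tnf and ENSMUSG00000089672 (0.287 each), Cxcr2 (0.351), Arpp21 (0.388), and Bcl6 and Clec12a (0.428 each). The mutant effect on Cd53 exceeded that in LT-HSC by 1.87 in ST-HSC, 2.75 in MPP3 and 2.93 in MPP4 on the log2 scale, and that on Cxcl2 by 5.63, 6.00 and 6.19. Without the number 1803, 18 genes passed, among them Cd53 (0.000501), Cxcr2 (0.00179), Clec12a (0.00296), Clec5a (0.0103) and Cxcl2 (0.0126). That number includes control LT-HSC replicate 4, so the control LT-HSC libraries left in this fit were the 3 high in S100a8. With the LT-HSC effect set against the mean of the other 3 populations, 11 of 27 lists passed, and 4 held with an estimated correlation. Erythroid, granulocyte-monocyte priming, and TNF and NF-kB genes fell further in LT-HSC (adjusted p = 0.0355, 0.0355 and 0.0122 with it), and megakaryocyte-platelet genes rose further (0.0406). Without the 3 control LT-HSC libraries high in S100a8 none of the 27 passed (smallest adjusted p 0.455).

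Across genes, which are not independent replicates, the mutant effects of 2 populations were correlated at r = 0.118 for LT-HSC and ST-HSC, 0.0938 for LT-HSC and MPP3 and 0.0453 for LT-HSC and MPP4. The value was 0.0185 for ST-HSC and MPP3, -0.000828 for ST-HSC and MPP4 and 0.0169 for MPP3 and MPP4. Spearman's rho was 0.0996, 0.0551, -0.0204, 0.0267, -0.0171 and -0.00466 in the same order. In the exact permutation test over the 35 splits of the 8 description numbers, two-sided, p ran from 0.171 to 0.971, and the 6 values adjusted together were at least 0.858. For LT-HSC and ST-HSC the other splits ran from -0.126 to 0.177. The smallest p this test can give is 0.0286. Within the 2 batches that the first digits of those numbers define, each population held at most 2 libraries of a genotype, and fits within a batch were not run.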

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

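The tests of the lists of mature cells and of the MPP3 identifier were chosen after the result was seen, and so was the choice of Xlr3b, which had the smallest p. The tests of Xlr3b and the gene list used for one of them were written with its p known but before their own values were seen, and the other splits were set before.

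The first pattern is the fall of mature-cell lists in mutant LT-HSC. Control libraries differed 616-fold in S100a8, and in 6 of 6 mature-cell lists the lowest control lay at or below the highest mutant library, so RNA of other marrow cells in 3 control libraries could account for these calls. Against it, no value was found. A lower multilineage transcription in mutant LT-HSC, the biological explanation, cannot be told apart from it, because only 1 control library is left at or under the S100a8 level. The higher long-term HSC list can follow from the same RNA, since counts are relative, and it was at an adjusted p of 0.67 without those 3 libraries.

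The second pattern is the MPP3 identifier, at 0 counts in the 4 mutant MPP3 libraries and at 221, 125 and 107 in control MPP3 replicates 1, 2 and 3. It had 0 counts in the mutant libraries of the other populations, but at most 1 count in their control libraries too. Only the MPP3 libraries therefore bear on its loss. Less B-lineage RNA in mutant MPP3 was not decided by summed Ighv RNA. In 1 of 4 mutant libraries it was less than in every control one, 2 lay within the control range and 1 above it, at 2780 CPM. The mature B cell list was at 4.921 ± 0.36 in mutant and 4.7 ± 0.42 in control MPP3, as log2(CPM + 1). Cd79a was at 85.92 to 150.2 CPM in mutant and 46.22 to 64.86 in control libraries. These values argue against a fall of mature B cell RNA as large as the identifier's, at least 53.9-fold. Of genes of antibody-secreting cells, Jchain was at 58.22 to 557.2 CPM in mutant and 138 to 508.8 in control libraries. Igkc was at 1081 to 13930 and 754.6 to 5355, and Prdm1 at 3.152 to 36.33 and 6.053 to 42.7. These ranges overlap and argue against a fall of that RNA as large as the identifier's. A smaller fall stays open, with mean Jchain at 230.5 ± 229 CPM in mutants and 359.3 ± 196 in controls. A strain variant at the heavy-chain locus stays open too: of 108 Ighv genes only 9 were over 1 CPM in every control MPP3 library, too few to decide, and 1 of these, Ighv6-3, stayed more than 10 times under the lowest control in every mutant one. Reads shared with Ighv6-3 remain open, and both may come from 1 variable segment. The 2 correlated at r = 0.932 over 29 libraries, but the identifier had over 1 count only in control MPP3 libraries. The correlation therefore restates the difference already seen there and cannot decide whether reads were shared. A clone of B cells was not tested.

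The third pattern is Xlr3b, higher in mutants of each population but at an adjusted p of 0.0686. Reads moved from Xlr3a to Xlr3b were excluded, since the summed Xlr3 family rose by 1.72 on the log2(CPM + 1) scale. Xlr3c had 0 counts in every library, so the sum held only Xlr3a and Xlr3b. It cannot exclude reads from copies outside it. A difference between the batches of the description numbers was excluded too, as Xlr3b rose by 1.98 and 1.46 within them. A relief of silencing that depends on DNA methylation, the biological explanation, stayed undecided. Of 32 other Xlr and germline genes 9 were tested, 5 higher and 4 lower, with a median log2 difference of 0.274 and a camera p of 0.0873 with an estimated correlation.

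Other splits of the samples were refitted for each comparison. With 0 genes called, any split gives as many by construction, so the splits test nothing for mutant LT-HSC, ST-HSC and MPP4 (35 of 35 splits each, highest other counts 484, 14 and 3) or for the average and the interaction (100 of 100, highest other 10 and 184). In MPP3, with 1 gene, 8 of 35 splits gave as many, with 7 as the highest other, so chance was not excluded. The 484 genes came from setting control LT-HSC replicates 1, 2 and 3 against the rest, and this count and the 184 point to a structure of the samples other than genotype. Among controls, chance was not excluded for ST-HSC against LT-HSC, where 3 of 35 splits reached 26 genes. The highest other, 218, set the same 3 LT-HSC libraries apart, again a structure of the samples. Chance was excluded for MPP3 against LT-HSC (218 genes, highest other 62), MPP4 against LT-HSC (627, highest other 14) and MPP4 against MPP3 (170, highest other 1), with 1 of 35 splits each.

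Counts of lists were adjusted over the 27 lists of 1 comparison here, so they differ from those of the report. Chance was not excluded for LT-HSC (17 lists, highest other 17, 3 of 35 splits), ST-HSC (3, highest other 8, 21 of 35), MPP3 (1, highest other 7, 27 of 35) or MPP4 (4, highest other 10, 18 of 35). For the average, 15 lists were called and the highest other was 16. There 2 of 100 splits, the real one included, gave as many, which passes the test at 5%. Of the first 40 and the first 50 of the same splits 2 each did, or 5%, which does not pass, and 4%, which does. The splits shuffled genotype within each population and ignored the description numbers that populations share, so they cannot exclude chance shared through those numbers. The result for the average therefore rests on the number drawn. The control LT-HSC libraries high in S100a8 also enter it, so an exclusion of chance does not make genotype the cause.

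Of 150 checks for a library far from the rest of its group, 13 were positive, where chance flags about 1 in 20 groups, or 7.5. Groups of 3 libraries, namely mutant LT-HSC, control ST-HSC and control MPP3, were not checked. The checks share libraries and some share genes, so they are not independent. Total counts were low in control LT-HSC replicate 4 (6438821, nearest other 8151317) and mutant MPP4 replicate 1 (7410008, nearest other 8576774). Dnmt3a was high in mutant MPP3 replicate 1 (222 CPM, nearest other 109), where the DNA methylation list was low (5.24, nearest other 5.34). Low list levels were also those of interferon genes in mutant MPP4 replicate 1 (3.85, nearest other 4.17), cytokine receptors in mutant ST-HSC replicate 1 (4.83, nearest other 5.24) and p53 targets in mutant ST-HSC replicate 2 (2.87, nearest other 3.28). High ones were those of p53 targets (3.39, nearest other 3.24) and macrophage genes (2.12, nearest other 1.75) in mutant MPP4 replicate 4, and of glycolysis in mutant ST-HSC replicate 2 (6.54, nearest other 6.08). The unfolded protein list (5.35, nearest other 4.76) and the dendritic list (3.17, nearest other 2.61) were high in control MPP4 replicate 2, and the stroma list in mutant ST-HSC replicate 4 (2.92, nearest other 2.12).

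For 4 lists the mutant effect in LT-HSC differed from the mean of the other 3 populations in a test of the difference itself, with an estimated correlation. The adjusted p was 0.0355 for the erythroid and for the granulocyte-monocyte list, 0.0122 for TNF and NF-kB response and 0.0406 for megakaryocyte-platelet genes. None passed without the 3 control libraries high in S100a8 (smallest 0.455).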

How the results depend on the processing

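The fits without the S100a8-high control LT-HSC libraries, with a neutrophil covariate, without immunoglobulin and rRNA-like genes, and without the 2 libraries with the fewest detected genes were chosen after the data were seen. The cause was not tested for any change below, except where fewer samples or another number of tested genes come with the setting. Groups of 3 or 4 limit what could be found: of genes simulated to change 2-fold, 16.4% were called in LT-HSC, 1.52% in ST-HSC, 12.1% in MPP3 and 30.6% in MPP4. These simulations held no differences between libraries that many genes share, so the real shares may be lower. Median-of-ratios scaling shifted the median log2 difference of a comparison by at most 0.0234 and left each count of genes within 1.5 times, but ended 3 ST-HSC list calls (G2 and mitosis, basophil and stroma, adjusted p = 0.0504 each). A sex term was not run, since no library expressed the Y-linked genes other than Uty.

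In mutant LT-HSC, where edgeR called 0 genes, 10 passed with no filter (0 higher), 292 in DESeq2, 75 in the fit of all 29 libraries (0 higher) and 10 with the neutrophil covariate. Without the S100a8-high libraries a lone control LT-HSC library is left, too few for a count. In MPP3, 2 passed in DESeq2, 2 in limma-voom with quality weights and 0 with the batch term, against 1. In MPP4, 1 passed with no filter and 5 in DESeq2. For the average, 4 passed with no filter and 3 in edgeR with no block, and for the interaction 48 in DESeq2. Control ST-HSC against LT-HSC had 52 genes with no filter, 308 in DESeq2 and 2 without the S100a8-high libraries, against 26. MPP3 against LT-HSC had 558 in DESeq2 and 111 without those libraries, and MPP4 against LT-HSC 1061 and 89. MPP4 against MPP3 had 468 in DESeq2. Of 46 list calls, 0 were left with an estimated correlation, and 8 ended without members that another list holds (0.0561 to 0.259). Without the S100a8-high libraries 14 list tests passed, of which 12 were among the 46 calls. These were 0 of 14 in LT-HSC, 3 of 9 in ST-HSC, 1 of 4 in MPP3, 3 of 5 in MPP4 and 5 of 14 for the average. Only the LT-HSC and averaged tests used those libraries. In their refit the lone control LT-HSC library is assumed to vary like the other groups. The ST-HSC, MPP3 and MPP4 tests hold no LT-HSC library, so their calls changed only through the adjustment over all 135 tests. The calls lost there had adjusted p values of 0.0565 to 0.0852, and they do not show a dependence on the S100a8-high libraries.

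The replicate block was the title's replicate number for the mutant comparisons and the description number for the interaction and the controls. With it, 398 genes passed in mutant LT-HSC, 5 of them higher, against 0 without it. Control LT-HSC replicate 4 has no mutant library of its number, so in that fit it carries no weight in the mutant difference. The fit thus resembles the one without that library, in which 384 genes passed. The other counts stayed within 1.5 times, with 1 gene in MPP3 although ENSMUSG00000094062 in MPP3 was then at an adjusted p of 0.195 in edgeR. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.175 to 0.0915 over 13 pairs, 0 of them over 0.1, and 6 of 26 libraries correlated best with their own number. For the description numbers the values were -0.152 to 0.175 over 39 pairs, 6 over 0.1, and 9 of 29.

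Leaving out 1 library gave 0 to 384 genes in mutant LT-HSC, 0 in ST-HSC, 0 to 1 in MPP3 and 0 in MPP4, and leaving out 1 description number 0 to 45 for the average and 0 to 18 for the interaction. Among controls it gave 1 to 217 for ST-HSC against LT-HSC, 63 to 247 for MPP3 against LT-HSC, 367 to 741 for MPP4 against LT-HSC and 78 to 157 for MPP4 against MPP3. List calls ran from 37 to 53. The log2 difference of Dnmt3a ran from -0.089 to 0.276 in LT-HSC, reversing also at -0.00221, from -0.193 to 0.0327 in ST-HSC, reversing also at 0.0206, from -0.203 to 0.324 in MPP3 and from 0.154 to 0.324 in MPP4.

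Without the S100a8-high libraries 6 LT-HSC lists reversed, namely lymphoid (adjusted p = 0.605), granulocyte-monocyte (0.895), immediate-early (0.403), neutrophil (0.0104), macrophage (0.465) and basophil (0.643), as did the averaged cytokine receptors (0.991), the averaged neutrophil list (0.532) and averaged Dnmt3a (-0.0495). The list lymphoid priming in ST-HSC reversed without control replicate 1 (0.854), and ran down to 6.17e-05 without control replicate 2. Correlations changed sign for ST-HSC and MPP4 (0.00852) and MPP3 and MPP4 (-0.013) over genes of at least 10 CPM, and by Spearman for LT-HSC and MPP4 (-0.0204) and MPP3 and MPP4 (-0.00466). Of 819 other values of list calls 634 stayed, 176 weakened and 9 reversed, and of 1462 values of named genes 1359 stayed, 40 weakened, 62 strengthened and 1 reversed.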

Other observations

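All values in this part were chosen after the data were seen, and no explanation was tested for them. MPP3 libraries of both genotypes held abundant immunoglobulin RNA. Ighm was at 9964 ± 6470 CPM in control and 11440 ± 8860 in mutant MPP3, and Igkc at 3167 ± 2310 and 5164 ± 5940. Jchain was at 359.3 ± 196 and 230.5 ± 229, and Cd79a at 58.11 ± 10.3 and 106.7 ± 29.7. In MPP4, Ighm was at 287.2 ± 51.3 in control and 247 ± 45 in mutant libraries and Igkc at 2.649 ± 1.98 and 0.7931 ± 0.537. Summed Ighv genes were at 1610, 223 and 807 CPM in control MPP3 replicates 1, 2 and 3 and at 312, 220, 751 and 2780 in mutant replicates 1, 2, 3 and 4.

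The splicing kinase gene Srpk1 ran from 250.9 to 8667 CPM across the 29 libraries, and Slx1b from 183.5 to 1584. Slamf1 was at 405.6 CPM in 1 mutant ST-HSC library, in a group at 102.3 ± 202. Mki67 was at 1725 ± 949 CPM in control LT-HSC, with libraries from 958.6 to 3111, against 594.4 ± 158 in control ST-HSC, 1384 ± 214 in MPP3 and 1162 ± 149 in MPP4. Xlr4b, of the same family as Xlr3b, had a log2 difference of 1.18 ± 0.386 (SE) in the averaged comparison, with an adjusted p of 0.796 in limma.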
